A study of Mus musculus with 8 samples.

How the data were processed

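Tumor endothelial cells were profiled by droplet single-cell RNA sequencing. Per the labels' protocols, fragments of MT-ret melanoma were implanted on the flank of 10 C57BL/6N mice, and blood endothelial cells (BEC) and lymphatic endothelial cells (LEC) were then separated by fluorescence-activated sorting, 10000 cells of each. The labels list 4 libraries per sort, made with the 10x Chromium 3′ v2 kit, in which each captured molecule carries a unique molecular identifier (UMI). The values used were raw UMI counts per gene and cell in 1 matrix deposited by the authors, with 28692 gene symbols and 7635 cells. Per the submitters' processing notes, Cell Ranger 2.1.1 and the mouse build mm10 were used; the authors' filter on cells is not given in the sources used here. No cell in the matrix was above 10% mitochondrial UMIs.

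The column names gave the sort of each cell and no library number, so the 4 libraries of a sort could not be separated and each sort was 1 sample. No test between the sorts was therefore possible, and no p-value, standard error or replicate check is given. UMIs were summed over the cells of each sort and expressed as CPM, the UMIs of a gene scaled to the total of its sort. Each CPM has an exact Poisson interval and each ratio an exact conditional binomial interval. Shares of cells have exact Clopper-Pearson intervals. All intervals are at the 95% level and cover counting error only, not differences between animals, sorts or libraries. Log2 ratios are of LEC over BEC with a pseudocount of 1 CPM. At the total depth of the sorts 1 UMI was worth 0.0140 CPM in BEC and 0.0169 CPM in LEC, so a count of 3 corresponded to 0.0421 and 0.0506 CPM.

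Before the data were examined, the rule for named genes, 21 gene lists, the cell type and subtype markers, the filter on cells and most of the alternatives were fixed. The rule named the 12 genes with the highest ratio in each direction, among genes at 50 CPM or more in the higher sort and at least 2-fold apart both in all cells and without clusters of non-endothelial type, ranked by the smaller of these 2 log2 ratios. Mitochondrial, ribosomal protein, haemoglobin and unnamed model genes were left out of that ranking. The rule also named all members of the angiopoietin-Tie list, the 4 members with the highest mean CPM of every other list, and the 10 leading genes of a described cluster. A list was summarised by the median log2 ratio of its members at 10 CPM or more and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. The result of 1 marker list is not reported here. The bounds of 5 and 95 used to count lists that stood apart were chosen after the values had been seen, and the count at bounds of 2.5 and 97.5 is given with it.

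The filter on cells (at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs) removed 0 cells. Cells of both sorts were clustered together. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes, scaled to unit variance with values limited to 10, were reduced to 30 principal components, and a shared-neighbour graph over 15 neighbours was partitioned by the Leiden algorithm at resolution 1 (scanpy 1.11.5, python-igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15; figures with matplotlib 3.10.9). Leading genes were ranked by fold over all other cells among genes at 50 CPM or more. After single cells were seen to drive some of them, a UMI in at least 25% of the cluster's cells was also required. The naming rule was likewise set after the data were seen. A cluster was named for a non-endothelial type if at least 3 of its 10 leading genes were markers of it, with fibroblast and mural markers pooled as stromal. Otherwise it was named BEC-like or LEC-like if at least 3 of that type's markers had a UMI in at least 50% of its cells and their share of the list was at least 2 times that of the other type, unless more leading genes were markers of another class than of its own. Clusters 8 and 11 each had 1 stromal marker (Tagln and Dcn) and no marker of their own type among the leading genes, and so stayed unnamed although 9 BEC markers and 9 LEC markers were detected in them. The doublet caller Scrublet called 0 cells in either sort and was taken not to have worked, so no doublets were removed.

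Own-type comparisons used BEC-like cells of the BEC sort and LEC-like cells of the LEC sort, and so left out clusters 8 and 11. Cycling cells were counted after each cell was thinned to 2000 UMIs, as cells with at least 2 UMIs from 10 cell cycle genes; no cell was too shallow. Gene positions came from the GENCODE M21 annotation of GRCm38, the assembly of mm10, and 27402 of the symbols matched it. The ratio, list and clustering steps were tested on simulated data. For simulated genes set apart by 1 and 2 log2 units in both directions, sums of 3139 genes were drawn from the Poisson model that the intervals assume. Of 50 intervals per group, 46 to 50 covered the true ratio. No variation between cells was simulated, so this does not show that the intervals hold for the real cells. A simulated list of 12 genes raised 2-fold reached percentile 100, and 100% of simulated cells fell in a cluster of their own group. That clustering used a lower resolution and fewer components than the real one, and splitting a group could not lower its score. It therefore does not test the clusters described below. Alternatives covered the filter, scaling, cell weighting, cell subsets, count minimum, pseudocount and clustering parameters, and their effects are in the closing section. A replicate block, another count model and leaving out single libraries needed the library of each cell and could not be run.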

Results

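Blood and lymphatic endothelial cells sorted from MT-ret melanomas, a transplanted mouse melanoma, were compared at the level of single cells. The BEC sort held 3228 cells with 71304111 UMIs, a median of 19416 UMIs per cell (6968 to 99171) and a median of 2845 genes. The LEC sort held 4407 cells with 59273049 UMIs, a median of 11000 UMIs per cell (5288 to 49210) and a median of 1938 genes. The median share of mitochondrial UMIs was 3.40% in BEC and 3.28% in LEC. Each sort was 1 sample from a pool of 10 mice, so the differences below have no replicate check and the intervals cover counting error only.

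Most cells of each sort carried the markers of their own lineage. BEC-like clusters held 85.4% of the BEC sort (84.2 to 86.6%) and LEC-like clusters 84.2% of the LEC sort (83.0 to 85.2%). Cells of the opposite type were few, with 91 BEC-like cells in the LEC sort (2.06%, 1.67 to 2.53%) and 26 LEC-like cells in the BEC sort (0.805%, 0.527 to 1.18%). Melanocytic-like cells, led by the pigment genes Dct, Tyrp1, Tyr and Pmel, made up 8.37% of the LEC sort (7.57 to 9.23%) and 0.682% of the BEC sort (0.428 to 1.03%). Stromal-like cells, led by genes such as Col3a1, Col1a1 and Rgs5, made up 1.08% of the BEC sort and 0.204% of the LEC sort. Clusters 8 and 11 stayed unnamed and together held 387 cells of the BEC sort and 229 cells of the LEC sort (5.20%). The cells had been sorted, so these are not shares of the tumor, and the shares of named and unnamed endothelial cells depended on the clustering, with 77.9% of the LEC sort LEC-like under another random seed. The melanocytic-like share of the LEC sort was 4.36% at resolution 2.

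**Figure D1:**
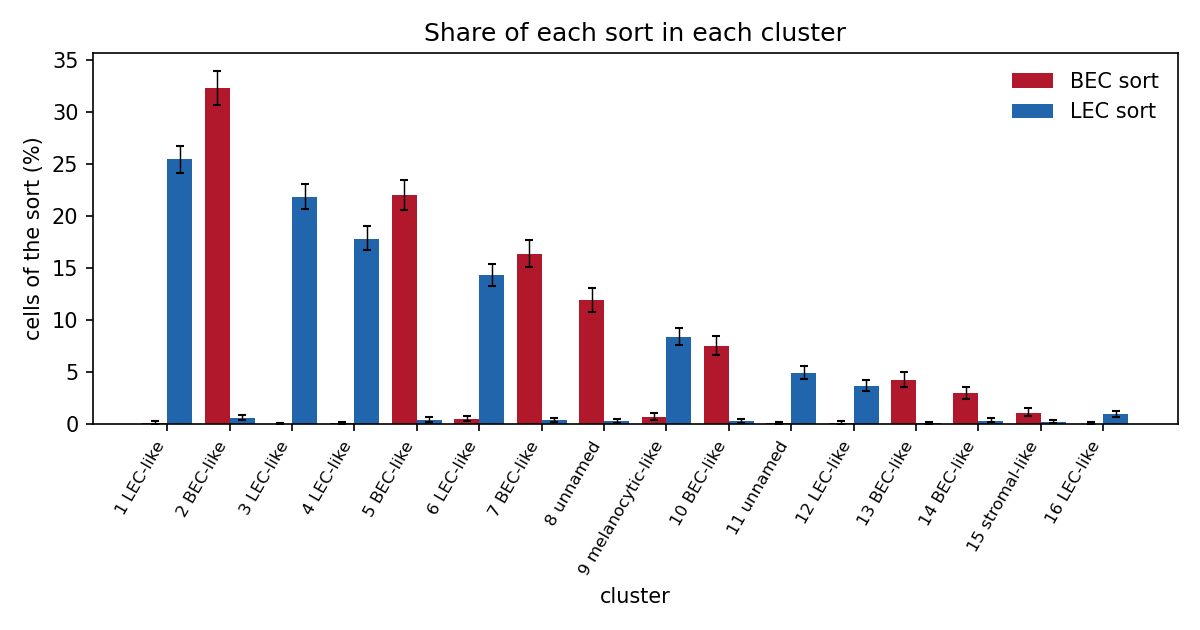
Share of the cells of the BEC sort (red) and the LEC sort (blue) in each of 16 clusters, in percent, with exact 95% binomial intervals for counting error. Nearly every cluster belongs to 1 sort, and melanocytic-like cluster 9 holds 8.37% of the LEC sort and 0.682% of the BEC sort.

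The LEC sort was set against the BEC sort to ask how the vessel types differ in the tumor. The lymphatic hyaluronan receptor Lyve1 (chromosome 7, 110850607 to 110863239, minus strand, GRCm38) was at 1713 CPM in LEC and 4.73 CPM in BEC, 363-fold higher (326 to 405). Podoplanin (Pdpn) was 201-fold higher (169 to 240), the secreted glycoprotein Reln 167-fold higher (133 to 211) and the multimerin gene Mmrn1 118-fold higher (108 to 130). In BEC, the apelin receptor Aplnr (chromosome 2, 85136225 to 85139923, plus strand) was 38.6-fold higher (35.5 to 42.0), the endothelial proteoglycan gene Esm1 31.3-fold higher (30.2 to 32.5), the VEGF receptor Flt1 28.9-fold higher (27.8 to 30.2) and Nrp1 29.1-fold higher (27.4 to 31.0). The other genes named by size were Npy, Ptx3, Ccl7, Ccl21a, Pard6g, Fgl2, Nts and Slc45a3 in LEC, and C1qtnf9, Fam167b, Tmem252, Plscr2, Col15a1, Col13a1, Cd93 and Ms4a6d in BEC. Ccl21a reached 21397 CPM in LEC, but near-identical Ccl21 copies exist in the genome and its value is uncertain. A single cell held 84.7% of the Npy UMIs of the BEC sort. In total 346 of 3553 genes at 50 CPM or more were at least 2-fold higher in LEC and 347 in BEC. With median-of-ratios size factors, which shift log2 ratios by -0.18 before the pseudocount and move some genes across the minimum, the split was 288 and 450. The 91 BEC-like cells of the LEC sort were counted in these ratios. Among cells of each sort's own type Aplnr was 316-fold, Flt1 305-fold, Nrp1 288-fold and Esm1 165-fold higher in BEC. Lyve1 was 1074-fold, Pdpn 957-fold, Reln 1125-fold and Mmrn1 500-fold higher in LEC. Except for Aplnr, these 8 genes are among the markers by which own-type clusters were named, so their own-type ratios depend in part on that choice.

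**Figure D2:**
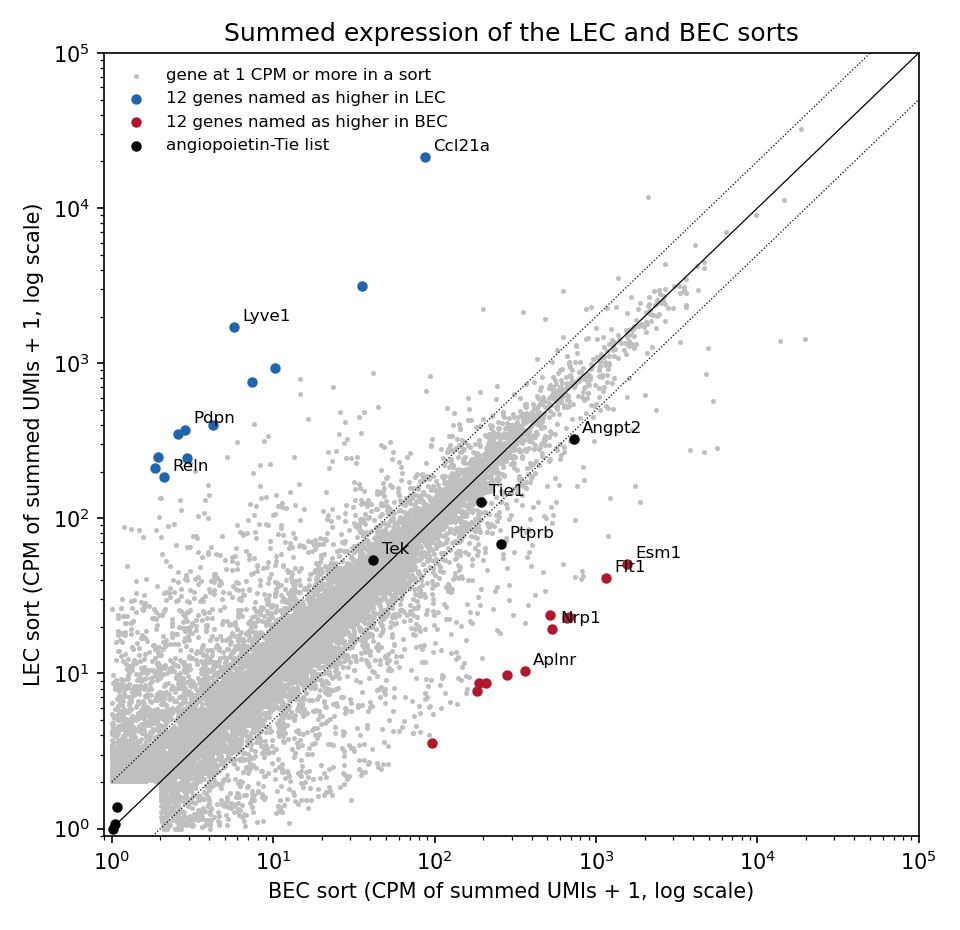
Summed expression per gene in the BEC sort (x axis) and the LEC sort (y axis), both as CPM + 1 on log scales; grey points are genes at 1 CPM or more in a sort, coloured points are the 12 genes named in each direction, black points are the angiopoietin-Tie list, the solid line is equality and dotted lines are 2-fold apart. Lyve1, 363-fold higher in LEC by CPM, lies far above equality, and Angpt2, 2.25-fold higher in BEC, lies below it.

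Genes of the angiopoietin-Tie pathway, which controls vessel stability, were mostly higher in BEC. The ligand Angpt2 (chromosome 8, 18690263 to 18741562, minus strand, GRCm38) was at 728 CPM in BEC (722 to 734) and 324 CPM in LEC (320 to 329), 2.25-fold higher in BEC (2.21 to 2.28). The phosphatase Ptprb, which acts on the receptor Tek, was 3.85-fold higher in BEC (3.72 to 3.99), and the receptor Tie1 was 1.52-fold higher (1.47 to 1.56). Tek itself (chromosome 4, 94739289 to 94874976, plus strand) was 1.29-fold higher in LEC (1.23 to 1.36), and 1.99-fold higher among cells of the sorts' own types. Angpt1, the agonist ligand, had 5 UMIs in BEC and 22 in LEC. Angpt4 had 3 and 4 UMIs, a ratio of 1.60 with an interval of 0.271 to 10.9, and Svep1 had 1 and 0 UMIs, so no difference in either was detectable at this depth. The Angpt1 ratio of 5.29 had an interval of 1.96 to 17.9, at 0.0701 CPM in BEC and 0.371 CPM in LEC. Its UMIs lay in 0.0620% of BEC cells and 0.159% of LEC cells, and 1 cell held 60% of those in BEC. This ratio therefore rests on few cells, and its interval does not cover differences between them. The median of the 4 members measured was -0.88 on the log2 scale, at percentile 1.64 of random lists.

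Within the sorts, Angpt2 differed between clusters by more than it differed between the sorts. It was at 1421 CPM in BEC-like cluster 7 (1401 to 1441) and 1210 CPM in BEC-like cluster 2 (1195 to 1225). In the LEC sort it was at 839 CPM in LEC-like cluster 4 (821 to 857) and 508 CPM in cluster 1 (496 to 521), against 51.1 CPM in cluster 3 and 46.5 CPM in cluster 6. Tek showed another order, with 117 CPM in cluster 6 and 116 CPM in cluster 8 against 18.7 CPM in cluster 7 and 24.0 CPM in cluster 2. Clusters 1 to 7, 9, 11 and 14 were redrawn by other clustering settings. Under at least 1 of these their best match shared as little as 0.398, 0.445, 0.340, 0.526, 0.312, 0.229, 0.220, 0.535, 0.350 and 0.105 of the cells of both (Jaccard index). Cluster 4 had 0.556 or less in 4 settings. For each of the other 6 clusters the lowest value was 0.802 or more.

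**Figure D3:**
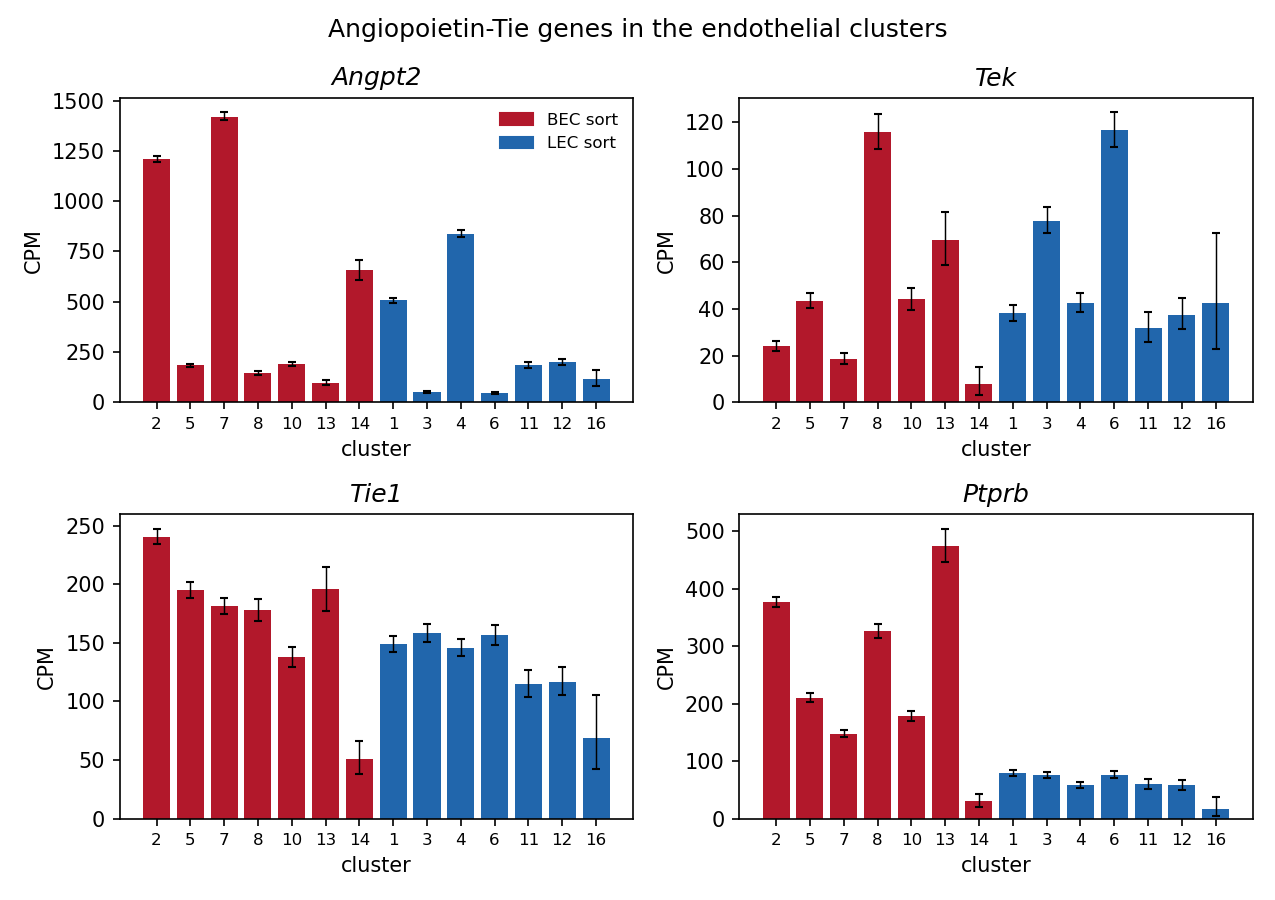
CPM of Angpt2, Tek, Tie1 and Ptprb (y axes, starting at 0) in each endothelial cluster (x axes), from the cells of the sort that holds most of the cluster, with exact 95% Poisson intervals; red bars are the BEC sort and blue bars the LEC sort. Angpt2 reaches 1421 CPM in cluster 7 and 839 CPM in cluster 4, and Tek reaches 117 CPM in cluster 6.

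Lists that were lower in LEC included vessel wall, Notch and lipid uptake genes. Of 12 basement membrane genes, 8 were at least 2-fold higher in BEC and 0 in LEC, with a median of -1.93 (percentile 0); Sparc was 10.0-fold higher (9.95 to 10.1), and 39.7-fold among own-type cells, and Col4a2 4.80-fold higher (4.70 to 4.90). Of 10 fatty acid uptake genes measured, 5 were higher in BEC and 1 in LEC, with a median of -1.68; the lipase anchor Gpihbp1 was 13.7-fold higher in BEC and Cd36 17.0-fold higher, and 22.1-fold and 29.7-fold among own-type cells, for which Cd36 was a naming marker. Of 10 Notch genes, 5 were higher in BEC and 1 in LEC (median -1.06), with Dll4 6.90-fold and Nrarp 8.13-fold higher in BEC. Of 14 BMP and TGF-beta genes, 7 were higher in BEC and 2 in LEC (median -0.98), with Eng 4.48-fold and Id1 3.61-fold higher in BEC. Of 9 leukocyte adhesion genes, 5 were higher in BEC and 1 in LEC (median -1.11), with Mcam 4.36-fold higher in BEC and 8.55-fold among own-type cells. Icam1 was 1.12-fold higher in BEC in all cells, and its own-type ratio of BEC over LEC was 0.807. Vcam1, the 1 adhesion gene higher in LEC, was 2.21-fold higher there in all cells. Among own-type cells its direction turned, with 10.6 CPM in BEC and 6.59 CPM in LEC. With only the non-endothelial clusters left out it stayed higher in LEC, at 46.1 CPM against 17.8 CPM in BEC. Own-type cells also leave out unnamed cluster 11, which had Vcam1 at 588 CPM against 12.8 CPM in all other cells of both sorts. The immune checkpoint median was -0.69 although 2 of 6 members were at least 2-fold higher in LEC and 1 in BEC. The cell junction median was -0.28, with Esam 14.6-fold higher in BEC and Cldn5 4.02-fold higher in LEC. Among own-type cells the medians of the basement membrane, fatty acid uptake, Notch, BMP and TGF-beta, leukocyte adhesion, immune checkpoint and cell junction lists were -2.15, -2.74, -0.94, -0.65, -0.99, -0.72 and -0.34.

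Lists that were higher in LEC included chemokine, MHC class II, hypoxia and immediate-early genes. Of 11 chemokine and scavenger genes, 6 were at least 2-fold higher in LEC and 2 in BEC, with a median of 1.49 (percentile 100). That median was 0.68 among own-type cells (10 members, percentile 97.2) and 0.98 with size factors (12 members). The monocyte attractant Ccl2 was 31.3-fold higher in LEC (29.8 to 32.9), and 16.7-fold among cells of the sorts' own types. All 3 MHC class II genes measured were higher in LEC, Cd74 by 10.2-fold (9.11 to 11.4) and by 3.52-fold among own-type cells. Without non-endothelial clusters Cd74 was at 58.9 CPM in LEC and 5.11 CPM in BEC. Own-type cells also leave out unnamed cluster 11, which held 4.95% of the LEC sort. Cluster 11 had Cd74 at 650 CPM and Ccl2 at 7936 CPM, against 9.44 and 132 CPM in all other cells of both sorts. A single cell held 66.9% of the Cd74 UMIs of the BEC sort. The 3 macrophage markers measured, Mrc1, Cd68 and Lyz2, were also higher in LEC (median 2.77). A single cell held 46.5% of the Lyz2 UMIs of that sort, while no cell held over 3.36% of those of Mrc1 or Cd68. Among own-type cells the macrophage list median was 3.26, and Mrc1 was at 24.5 CPM in LEC and 0.195 CPM in BEC. The 5 pan-leukocyte markers summed to 3.42 CPM in the LEC sort and 8.02 CPM in the BEC sort. Their members went both ways. Cd52 was at 0.112 CPM in BEC and 1.05 CPM in LEC and Ptprc at 0.0701 and 0.253 CPM, but Laptm5 was at 1.33 and 0.827 CPM. The sum therefore does not decide whether the LEC sort held more leukocytes. Of 9 hypoxia genes, 6 were higher in LEC and 0 in BEC (median 1.11, percentile 99.97), with Adm 2.17-fold, Higd1a 2.20-fold and Ndrg1 2.01-fold higher. Among cells of the sorts' own types, which leave out the melanocytic-like cells, the list median was 0.90 and those 3 ratios were 1.84, 1.91 and 2.80. Fos was 2.59-fold, Klf2 2.49-fold and Klf4 3.41-fold higher in LEC; the dissociation stress list, which holds Fos, had a median of 0.67, and 0.82 among own-type cells. The sphingosine 1-phosphate list had a median of 0.79, with the kinase Sphk1 18.2-fold higher in LEC and 35.6-fold among own-type cells. The list median was 0.44 among own-type cells. With size factors it was 0.02, over 4 members in place of 5, and 0.62 over the same 5. The transcription factor list had a median of 0.29, and 0.55 among own-type cells (percentile 100). With size factors it was -0.04, over 22 members in place of 23, and 0.12 over the same 23.

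Other lists had no single direction. Of 11 guidance genes, 4 were at least 2-fold higher in BEC, such as Robo4 (6.11-fold), and 3 in LEC. Sema3d (74.6-fold, and 562-fold among own-type cells) and Sema3a (32.5-fold) were among the latter, both picked out after their values were seen. The guidance median was -0.21 (percentile 4.405), and -0.10 among own-type cells (percentile 16.1). VEGF genes divided evenly, with Flt4, the lymphatic VEGF receptor, 6.02-fold higher in LEC and Kdr 2.31-fold higher in BEC; the median was 0.07, 0.32 among own-type cells and -0.10 with size factors. Paracrine factors divided into 5 genes at least 2-fold higher in LEC, such as Ccl21a and Reln, and 5 higher in BEC, such as Apln (14.6-fold) and Cxcl12 (12.9-fold), at 88.5-fold and 26.1-fold among own-type cells. Their median was -0.27 in all cells and 1.99 among cells of the sorts' own types, where Rspo3 passed the minimum as an 11th member. The glycolysis median was 0.05, but -0.13 with size factors and -0.21 among own-type cells. MHC class I genes had a median of -0.13, with B2m 1.03-fold higher in BEC, and of -0.059 among own-type cells. The interferon list had a median of -0.16 (percentile 7.14), and of -0.31 among own-type cells (percentile 1.83). Own-type cells leave out cluster 11, in which all 11 interferon genes were at least 2-fold higher than in other endothelial cells of the LEC sort. Markers of the sorted types had medians of -4.21 for BEC and 6.50 for LEC, and pan-endothelial markers of -0.57. Melanocytic markers had a median of 3.08 and mural markers -2.42. Fibroblast, dendritic, neutrophil, T and NK, B cell, pan-leukocyte, keratinocyte, erythroid, platelet, skeletal muscle and adipocyte lists had at most 2 members at 10 CPM in all cells, too few for a median. Among own-type cells 3 platelet markers passed that minimum, with a median of 2.53.

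**Figure D4:**
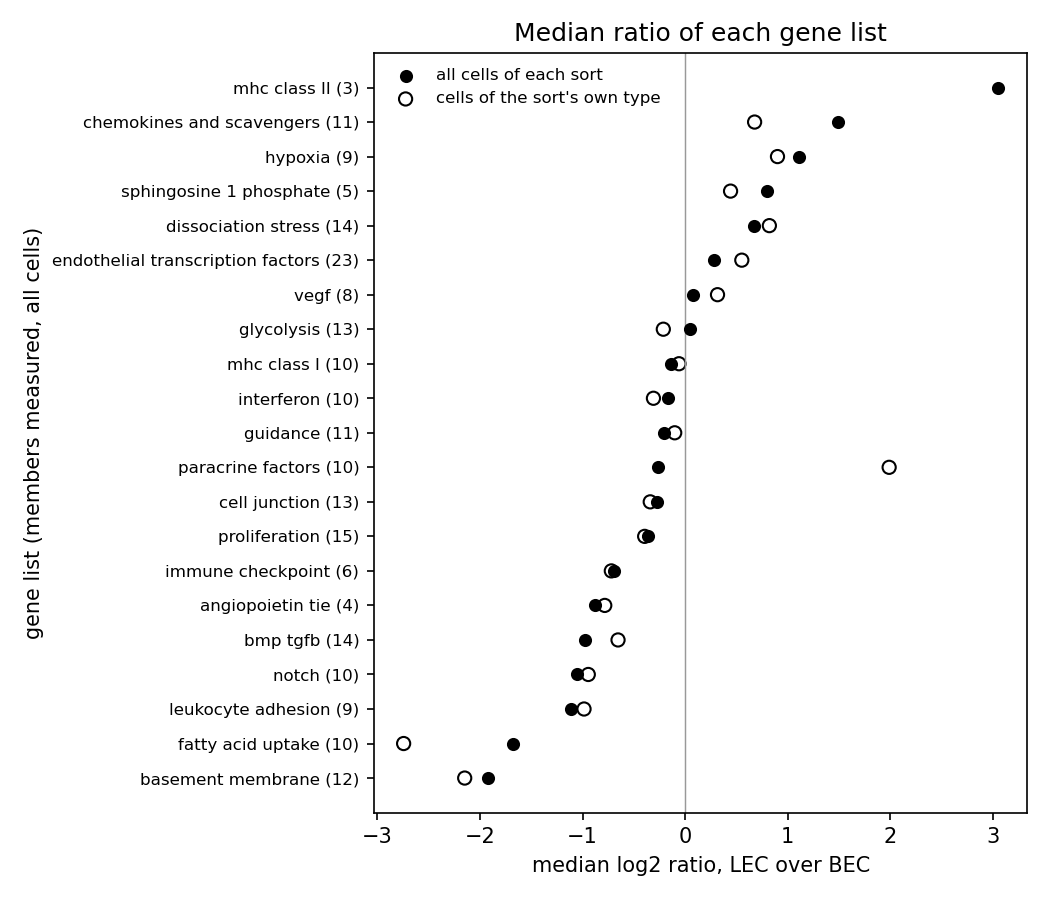
Median log2 ratio of LEC over BEC (x axis) for each of 21 gene lists (y axis, with the number of members measured in all cells); filled points use all cells of each sort and open points the cells of the sort's own type, with none for MHC class II, which had only 2 members measured there. Basement membrane genes lie lowest in all cells at -1.93, and paracrine factors move from -0.27 to 1.99 between the 2 sets of cells.

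The endothelial cells fell into 14 clusters, described by number and leading genes. Clusters were drawn from all variable genes, so list members outside the leading genes may also have shaped them. The list counts and medians below describe the clusters and are not independent results. In the BEC sort, cluster 2 (32.4% of cells) was led by genes such as Npr3, Vegfc and Esm1, cluster 5 (22.0%) by Aplnr and Ramp3, and cluster 7 (16.4%) by Tnfrsf9, Apln and Kit. Cluster 8 (11.9%) was led by Ackr1, Sele, Selp and Vwf, with Tagln, a mural marker, among its leading genes. Of 7 venous markers 6 were at least 2-fold higher in it than in other endothelial cells of the sort, 3 of which are among the genes that define it. Cluster 13 (4.21%) was led by genes such as Aqp7 and Gja5, and 9 of 10 arterial markers were higher in it, with a median of 2.84; 1 of them, Gja5, defines the cluster. In the same cluster 9 of 14 dissociation stress genes (median 1.16), 4 of 7 capillary markers (median 1.62) and 6 of 9 fatty acid uptake genes were also at least 2-fold higher. Of these, Car4 among the capillary markers, and Tcf15 and Lpl among the fatty acid uptake genes, define the cluster. In the LEC sort, cluster 1 (25.5%) was led by Cd24a and Scn3a, cluster 3 (21.9%) by Tppp3 and Igfbp5, and cluster 6 (14.3%) by Lsr, Postn and Foxp2. Cluster 4 (17.9%) was led by Npy, Ndufa4l2 and Pgf, with 9 of 10 hypoxia genes, 1 of them (Egln3) a defining gene, and 14 of 14 glycolysis genes (median 1.61) at least 2-fold higher than in other endothelial cells of that sort. Cluster 11 (4.95%) was led by Cd74, Ccl2 and H2-Aa. Cluster 7 of the BEC sort had 4 of 8 hypoxia genes higher (median 1.29). Clusters 14 and 16, with 2.94% of BEC and 0.930% of LEC, had median mitochondrial shares of 0.0593% and 0.0432%.

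Cycling cells were present in both sorts. After thinning, 9.60% of BEC (8.61 to 10.7%) and 6.42% of LEC (5.72 to 7.19%) had at least 2 UMIs from the cell cycle genes; without thinning the shares were 42.8% and 20.1%. The summed level of these genes was 480 CPM in BEC and 357 CPM in LEC. Outside clusters 10 and 12, in which all 10 cell cycle genes were higher, the thinned shares were 3.72% of BEC and 3.31% of LEC, at median depths of 18886 and 10866 UMIs. The proliferation list had a median of -0.36, with Cdk1 2.63-fold higher in BEC and 14 of 15 members within 2-fold.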

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

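The tests on swapped barcodes, free RNA and both explanations for melanocytic-like cells were chosen after the result was seen. Cells of types outside the sort drew attention as a signal that the comparison of the sorts does not use. Melanocytic-like cells were 8.37% of the LEC sort and 0.682% of the BEC sort, and stromal-like cells 1.08% of the BEC sort and 0.204% of the LEC sort. The bound for a closer look was the share that a count of 0 allows (0.0681% in LEC and 0.0929% in BEC), which any cluster of more than 3 cells of a sort passes, so passing it is no evidence on the origin of these cells. At resolution 2 the melanocytic-like share of the LEC sort was 4.36%. In addition 34 cell barcodes occurred in both sorts.

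The melanocytic-like cells of the LEC sort carried lymphatic RNA. If they were droplets that also held a LEC, lymphatic markers would be a large part of their level in LEC-like cells, but the median over 9 markers was 0.102 of it, below the 0.2 that was set as the bound. Fgl2 was an exception at 0.591, and the next highest was Thy1 at 0.134. These levels were pooled over the 369 cells, so a minority of droplets that also held a LEC cannot be excluded. In the 22 melanocytic-like cells of the BEC sort Fgl2 was at 109 CPM and in 59.1% of cells, above its level in BEC-like cells. Lyve1, Pdpn, Mmrn1 and Reln had 0 UMIs there, while Prox1, Flt4, Ccl21a and Thy1 had 1, 7, 11 and 5. Fgl2 RNA in melanocytic-like cells therefore need not come from LEC. If the melanocytic cells made Pdpn RNA themselves, its ratio would lie above those of the other markers, but at 0.0843 it lay below their range (0.0875 to 0.591). RNA says nothing of the protein that the sort read. Neither impurity of the sort nor free RNA as the source of the lymphatic markers in these cells was tested. Apart from Pdpn RNA in these cells, no biological explanation was tested.

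The LEC sort also held 91 BEC-like cells. Barcodes swapped between libraries would put the same barcodes in both sorts, but 0% of these cells (0 of 91, which allows up to 3.30%) carried a barcode of the BEC sort. Droplets with both cell types would carry lymphatic markers at 0.33 or more of their level in LEC-like cells, but the median over 9 markers was 0.0654. This level was pooled over the 91 cells, so a minority of such droplets among them cannot be excluded. Free RNA in all droplets would put BEC markers in LEC-like cells at 0.5 or more of their level in these cells, but the median over 10 markers was 0.0205, with Plvap highest at 0.204. Such RNA, mostly of LEC in this sort, would not lower the lymphatic markers either. The markers in both tests had also been used to name the clusters. Impurity of the sort stays open, and no biological explanation was tested.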

How the results depend on the processing

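Alternatives that left out the 5% of cells with the most UMIs, cells under 0.5% mitochondrial UMIs or barcodes found in both sorts were chosen after seeing the data, as were the list bounds of 5 and 95. No paired analysis was possible because the columns carry no library number; for the same reason a replicate block, another count model and leaving out libraries were not possible. Removing no cells by filter, and the called doublets, of which there were 0, changed nothing by construction. With a minimum of 5 CPM, 1228 genes were higher in LEC and 815 in BEC, and with 100 CPM 212 and 223, since other numbers of genes entered. Of 21 lists 17 lay outside percentiles 5 and 95, and 13 outside 2.5 and 97.5. With a minimum of 100 CPM, 11 of the 15 lists with a median lay outside 5 and 95. The paracrine median of -0.27 became 1.82 with the mean over cells, 1.88 without non-endothelial clusters, 1.99 with own-type cells, 1.74 and 1.45 with minimums of 5 and 100 CPM, and 1.75 without the cells with the most UMIs. The list had 5 genes in each direction; 11 members passed the minimum in each of these settings except that of 100 CPM, where 4 did. The transcription factor median became -0.040 with size factors, as 22 members passed the minimum in place of 23; over the same 23 it was 0.12. Own-type shares were 87.4% of LEC at resolution 0.5, with 1.97% unnamed. At resolution 2 they were 72.6% of BEC and 79.6% of LEC, with 25.0% and 13.3% unnamed and 4.36% melanocytic-like in LEC. With 15 components 79.3% of LEC were LEC-like and 10.1% unnamed. With 50 components 82.7% of BEC and 79.6% of LEC were of their own type, with 14.7% and 9.85% unnamed. Another seed gave 77.9% LEC-like and 11.5% unnamed in LEC; the cause was not tested. Cycling shares in BEC and LEC were 6.47% and 3.95% after thinning to 1000 UMIs, 14.99% and 9.89% at 4000 UMIs, 20.4% and 12.8% with 1 UMI, 6.94% and 4.52% with 3 UMIs, by construction of the threshold, and 8.51% in BEC without the cells with the most UMIs. BEC had the higher share in each of these. Of 66 named genes at least 2-fold apart, 0 changed direction in 11 alternatives and 8 fell under 2-fold in at least 1: Adm, Angpt2, Cdh5, Higd1a, Icam2, Id3, Ndrg1 and Vsir.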

Other observations

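In the LEC sort, unnamed cluster 11 (4.95% of cells) was led by Cd74, Ccl2, Ccl7 and H2-Aa, which define it and are not a result. All 11 interferon genes, of which Gbp2 also defines the cluster, were at least 2-fold higher in it than in other endothelial cells of that sort, with a median of 1.60, and Icam1 was at 379 CPM. The best match of this cluster shared 0.350 of the cells of both at resolution 0.5 and 0.496 at resolution 2. These levels are of 1 sample, and Dcn, a fibroblast marker, was among its leading genes. The cluster was drawn from all variable genes, so interferon genes other than Gbp2 may also have shaped it. Their higher levels describe the cluster and are not an independent result.

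A single cell decided the level of the chemokine Ccl8, a gene singled out after its values were seen. It held 94.3% of the 4982 Ccl8 UMIs in the LEC sort, with 242 UMIs of C1qa and 400 of Lyz2, both macrophage markers, 1 of Prox1 and 0 of Pecam1. It lay in LEC-like cluster 4. No other gene at 50 CPM or more in LEC, and none in BEC, had 50% or more of its UMIs in 1 cell.

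The tests below on cells with almost no mitochondrial RNA were written before their values were seen, except that the direction in the depth test was read afterwards. Cells under 0.5% mitochondrial UMIs were 139 BEC (4.31%) and 92 LEC (2.09%). The nuclear RNA Malat1 was at 1355 CPM in them against 19027 CPM in the other BEC, and at 3508 against 32932 CPM in LEC. Xist, Kcnq1ot1, Neat1 and Meg3 were also lower, and all 5 had been looked at before any test was set. Gal, not among the nuclear RNAs but also looked at by then, was 8.86-fold higher in these BEC and 24.6-fold higher in these LEC. Over 77 ribosomal protein genes, not part of the test, the median log2 ratio was 0.386 in BEC and 0.438 in LEC. Droplets without a nucleus may account for the lower nuclear RNAs. The test named 6 nuclear RNAs not yet looked at, of which 3 were in the data. Their median log2 ratio was -0.16 in BEC and -2.09 in LEC, from 0 to 6 UMIs per gene, which is too few to decide. Low depth alone is argued against, since ordinary cells as shallow as these had higher Malat1 than deeper cells, by 1.04 log2 units in BEC and 0.69 in LEC. The bound set in advance was a difference within 1 unit, which BEC exceeded in the direction opposite to that explanation. No biological explanation was tested.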
